A study of Homo sapiens with 6 samples.

How the data were processed

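Total RNA was taken from HEK293 cells labelled control or MOCS2 knockdown, and stranded libraries were made after ribosomal RNA removal with Ribo-Zero Gold, per the labels' protocols. The authors deposited 1 table of raw read counts per Ensembl gene, with 6 columns of 3 control and 3 knockdown libraries. Per the submitters' processing notes, bcl2fastq 2.18, TopHat2 2.0.13 and HTSeq were used with the hg38 build. The HTSeq version, the annotation release, the strand setting and any read filter are not given in the sources used here. The counts are whole numbers whose totals differ between libraries, and they were not normalized before deposit.

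The table has 60675 gene rows and 5 special HTSeq rows for reads not assigned to a gene. The special rows were kept out of library sizes and tests. Reads outside genes made up 23.6%, 23.9% and 24.9% of uniquely aligned reads in control replicates 1, 2 and 3, and 22.3%, 37.5% and 21.5% in knockdown replicates 1, 2 and 3. Gene symbols and coordinates were taken from GENCODE release 29 (GRCh38) by Ensembl identifier, which matched 57055 identifiers and left 3620 without a symbol. Of 988 entries in 31 gene lists, 987 were matched. Group and replicate number come from the sample titles.

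Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter, and a quasi-likelihood F test of knockdown against control (two-sided), adjusted by Benjamini-Hochberg with a threshold of 0.05. The filter left 18267 genes. CPM values are scaled by the TMM factors, and log2 CPM used a prior count of 2. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. For each list, members were also adjusted over the list alone. This was not corrected over the 31 lists, in which 106 members passed in all. A count over the list alone therefore does not by itself set a list apart from other genes. The test, the lists, the alternatives and the rule for named genes were chosen before the data were examined.

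The rule named MOCS2, the 12 largest positive and 12 largest negative log2 fold changes past the adjusted threshold with a mean of at least 2 CPM and no overlap between groups, up to 4 members past the threshold per list or else the 2 most abundant, and measured members of the molybdenum cofactor, sulfur and APP lists. Because 0 genes passed, the second part was relaxed, after the values were seen, to an unadjusted p under 0.001, and list members were taken by the adjustment over the list alone.

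On simulated counts with 200 changed genes among 17924 tested, made for this comparison with the estimated dispersion, the test recovered 65.3% of genes changed by a log2 fold change of 1 and 99% of those changed by 2, with 12 false calls. Both groups were simulated with the same dispersion per gene, and genes were drawn independently. The real libraries labelled knockdown spread more widely than the controls, so these rates need not hold for the real data. In the list simulation, the 1 shifted list was called and 0 of 30 others. Genes were drawn independently there, while the estimated correlation within the real lists reached 0.76 for histones and 0.34 for cholesterol synthesis. The simulation therefore does not give the rate of false list calls in these data. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom from 11.4 to 74.1), so each was counted as a sample. The common biological coefficient of variation was 0.206. The median SD of log2 CPM was 0.124 among controls and 0.262 among the libraries labelled knockdown.

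The alternatives were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0, limma voom, no filter, at least 1 CPM in 3 libraries, glmTreat against a log2 fold change of 0.5, the replicate number as a block, and leaving out each library. GC and length offsets and protein-coding genes only were added after seeing the data. DESeq2 gave no adjusted p for 1774 genes, which were not counted as calls. Isoforms of MOCS2 cannot be separated in counts per gene, and protein was not analysed here. Some list members that the rule names are not reported here.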

Results

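The series holds total RNA sequencing of HEK293, an established human cell line of embryonic kidney origin, in 3 libraries labelled control and 3 labelled MOCS2 RNAi knockdown. MOCS2 encodes both subunits of molybdopterin synthase, an enzyme of molybdenum cofactor synthesis. The title ties a complex named MPTAC to sulfur amino acid breakdown and to fragments of APP, the amyloid precursor protein, and the comparison asks which transcripts differ when MOCS2 is targeted. Reads assigned to genes numbered 21916142, 22171106 and 19895547 in control replicates 1, 2 and 3, and 18726700, 17958632 and 19362299 in the libraries labelled knockdown. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

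MOCS2 RNA was not lower in the libraries labelled knockdown. MOCS2 (ENSG00000164172, chromosome 5, 53095679 to 53110063, minus strand, GRCh38) stood at 57.8, 66.5 and 65.6 CPM (counts scaled to the library size) in the controls and at 69.8, 58.9 and 59.9 CPM in the libraries labelled knockdown. The means were 63.3 ± 4.83 and 62.9 ± 5.99 CPM (SD over 3 libraries), a log2 fold change of -0.01 with a standard error of 0.14 (edgeR adjusted p = 0.976) and a 95% interval, on 4 residual degrees of freedom, that reaches down to -0.41. The targeted gene therefore goes against the label, and every direction that follows is that of the libraries labelled knockdown against the controls, not of a measured loss of MOCS2 RNA. The sign of this value turned positive when control 2, control 3, knockdown 2 or knockdown 3 was left out, and the values ran from -0.094 to 0.027.

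Other genes of molybdenum cofactor synthesis and of the enzymes that use it did not pass the test either. MOCS1, which acts at the first step, averaged 24.1 ± 3.97 CPM in controls and 16.9 ± 5.65 CPM in the libraries labelled knockdown. GPHN, which inserts molybdenum, averaged 30.8 ± 1.76 and 40.9 ± 5.22 CPM, and SUOX, the sulfite oxidase, 18.7 ± 1.58 and 15.4 ± 2.65 CPM. Of 11 measured members of this list, 0 passed edgeR's test over all genes and 0 passed when adjusted over the list alone, and the list as a whole had a median log2 fold change of -0.21 (camera adjusted p = 0.457, and adjusted p = 0.88 with an estimated correlation). AC008966.1, listed as MOCS2-DT in a newer symbol table, starts inside MOCS2 on the opposite strand (chromosome 5, 53109842 to 53115126) and averaged 6.95 ± 0.727 CPM in controls and 3.53 ± 1.45 CPM in the libraries labelled knockdown (log2 fold change -0.98, standard error 0.31, edgeR adjusted p = 0.134, DESeq2 adjusted p = 0.0387). This fold change was singled out after it was seen, and it is uncertain because the strand setting of the counting is not given in the sources used here.

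Across single genes, SERPINB2, an inhibitor of plasminogen activators, averaged 0.48 ± 0.383 CPM in controls and 22.4 ± 28.0 CPM in the libraries labelled knockdown (log2 fold change 5.55, standard error 1.15, edgeR adjusted p = 0.0767). Its value rests largely on knockdown 1, at 54.2 CPM against 11.5 and 1.48 CPM in the others, and was 3.76 without it and 6.21 without control 3. PKP3, a desmosomal plakophilin, averaged 7.76 ± 5.87 and 0.196 ± 0.132 CPM (log2 fold change -5.25, standard error 0.90, adjusted p = 0.0661). PUDP, a pseudouridine phosphatase, averaged 10.7 ± 1.79 and 2.11 ± 0.533 CPM (log2 fold change -2.34, standard error 0.27), and LUM, the proteoglycan lumican, 11.9 ± 4.71 and 1.9 ± 0.685 CPM (-2.64, standard error 0.38). Both had an edgeR adjusted p of 0.0558, the smallest of all genes. Other genes with higher values in all 3 libraries labelled knockdown than in all 3 controls were CTGF (17.6 and 173 CPM), KRT17 (9.45 and 63.4 CPM), PCSK1 (4.7 and 28.4 CPM), SLC7A3 (1.42 and 9.33 CPM), CRMP1 (4.26 and 17.2 CPM) and TAGLN (2.97 and 12.9 CPM). Genes with lower values in all 3 were CNTN1 (39.7 and 8.77 CPM), SULT1A1 (46.2 and 9.62 CPM), PIR (12.03 and 2.62 CPM) and PTPRZ1 (4.6 and 0.487 CPM). Leaving out 1 library moved the log2 fold change of CTGF from 3.30 to 2.22 (without knockdown 1), of KRT17 from 2.75 to 3.34 (without control 3) and of PTPRZ1 from -3.23 to -2.43 (without control 2). SULT1A1 has near-identical paralogs and its counts are uncertain.

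None of these genes passed the threshold fixed in advance with edgeR on all 6 libraries. DESeq2 called 61 of the 77 genes named by the rules, SERPINB2 (adjusted p = 0.0049), PUDP (1.76e-11), LUM (2.31e-09) and PKP3 (0.000566) among them, but voom called 0 of them. PKP3 (0.00185), PTPRZ1 (0.0307) and PUDP (0.0384) passed edgeR without control 3, 64 of the 77 without knockdown 3, 60 with no filter and 7 with the replicate block. Over 18267 tested genes, edgeR's quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p of 0.05. At an unadjusted p of 0.05 it had 1813 higher and 1933 lower, 20.5% of the genes tested, where chance alone gives 5%. DESeq2 called 559 higher and 586 lower, and limma voom called 0. The groups did not overlap in 2283 genes above and 2617 below the controls, 26.8% of genes, where chance gives 10%. The count depends on 1 library: without the library labelled knockdown 3, edgeR called 1232 genes higher and 1583 lower, while leaving out any other library gave at most 4 calls. The genes named in the previous paragraph were drawn from 151 genes with an unadjusted p under 0.001, a rule relaxed after it was seen that no gene passed. These 151 also had to meet the rule's minimum mean CPM, a filter on gene names and types, and no overlap between groups. The lack of overlap in the named genes is therefore a condition of their choice and not a result.

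**Figure D1:**
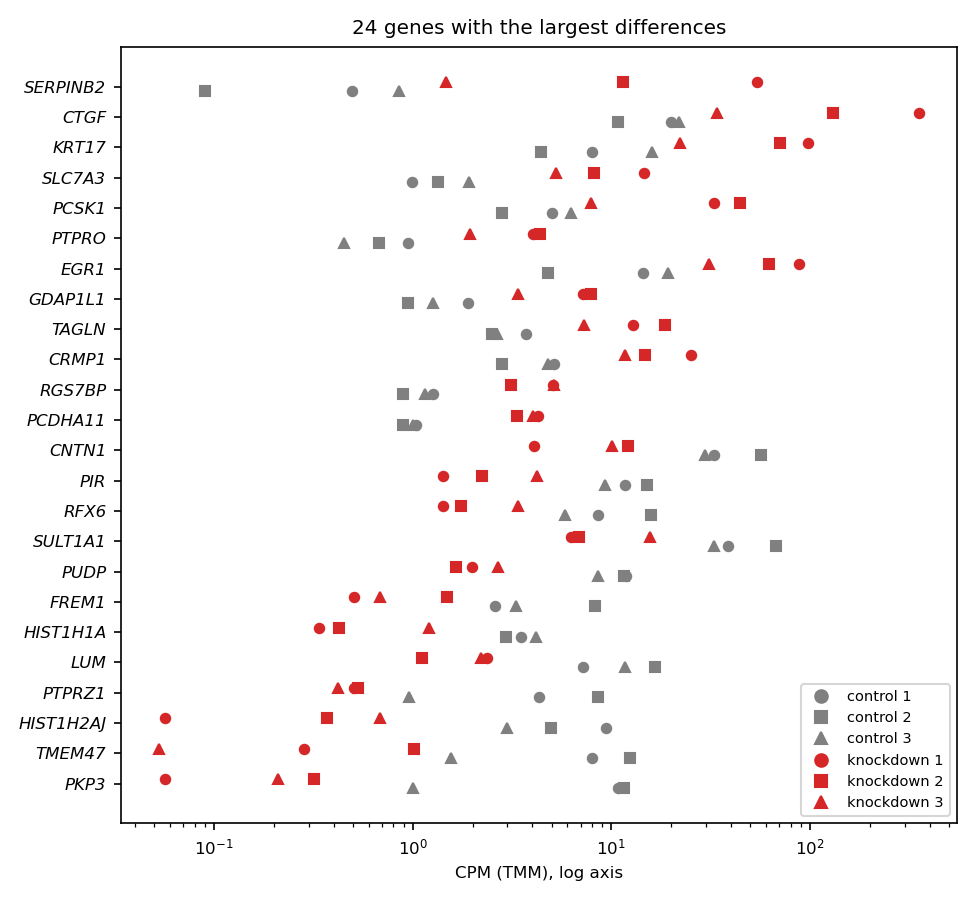
Levels in CPM (TMM-scaled, log axis) of 24 genes in each of the 6 libraries, controls in grey and libraries labelled knockdown in red, with a marker shape for each replicate number. The 12 genes with the largest positive and the 12 with the largest negative log2 fold change of the pool are drawn, from SERPINB2 at 0.48 and 22.4 CPM on average to PKP3 at 7.76 and 0.196 CPM. In each the groups do not overlap, which the rule for the pool required.

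Replication-dependent histone genes, whose transcripts accompany DNA synthesis, were lower in the libraries labelled knockdown throughout the list. All 25 measured members had a negative log2 fold change and 25 fell when adjusted over the list alone, with a median of -1.19. HIST1H2BO averaged 74.4 ± 15.4 CPM in controls and 22.4 ± 15.3 CPM in the libraries labelled knockdown, HIST1H2AM 21.5 ± 2.74 and 7.49 ± 4.57 CPM, and HIST1H3A 99.1 ± 9.19 and 28.9 ± 24.2 CPM. The linker histone HIST1H1A averaged 3.55 ± 0.609 and 0.659 ± 0.482 CPM. Camera gave an adjusted p of 1.92e-22 for the list (adjusted p = 0.65 with an estimated correlation), and edgeR called 0 members over all genes. The list medians of the 3 libraries labelled knockdown were -1.85, -1.89 and -0.42 relative to the control mean, and the number that fell was 1 of 25 without knockdown 1, 20 without knockdown 2 and 24 without any of the other 4 libraries. Without knockdown 3 the log2 fold change of HIST1H2BO moved from -1.73 to -2.46, of HIST1H2AM from -1.52 to -2.15, of HIST1H3A from -1.78 to -2.73 and of HIST1H1A from -2.41 to -3.19. Histone genes share long identical stretches, so values of single members are uncertain. The cell cycle list did not pass (median -0.27, camera adjusted p = 0.057, adjusted p = 0.83 with an estimated correlation), with TOP2A at 1248 ± 166 and 645.4 ± 433 CPM and list medians of -0.17, -0.69 and -0.03 in knockdown 1, 2 and 3. It passed without control 1 (0.0234), control 3 (0.021), knockdown 1 (0.00462) or knockdown 3 (4.38e-12, with 19 members falling and 4 rising over the list alone).

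Immediate early and AP-1 genes, which respond rapidly to growth factors and stress, were higher, mainly in knockdown 1 and 2. Of 30 measured members, 17 rose and 0 fell when adjusted over the list alone, and 29 had a positive log2 fold change (median 0.80). EGR1 averaged 12.8 ± 7.37 CPM in controls and 60.6 ± 28.7 CPM in the libraries labelled knockdown, FOSL2 28.98 ± 4.63 and 79.2 ± 33.2 CPM, CYR61 27.3 ± 6.92 and 131.8 ± 96.0 CPM, and CTGF 17.6 ± 5.93 and 173 ± 164 CPM. Camera gave an adjusted p of 5.58e-12 (adjusted p = 0.65 with an estimated correlation), and edgeR called 0 members over all genes. The list medians were 1.11, 1.06 and 0.24 in knockdown 1, 2 and 3, against 0.20, -0.38 and 0.23 in control 1, 2 and 3. By this median, knockdown 3 was level with control 1 and 3. The number of members that rose was 0 without knockdown 1, 6 without knockdown 2, 5 without control 2, 16 without control 1, 17 without control 3 and 21 without knockdown 3. The log2 fold change of CYR61 was 2.27, and 1.64 without knockdown 1. Cytosolic heat shock and chaperone genes had a median of 0.23 (camera adjusted p = 0.0146, adjusted p = 0.65 with an estimated correlation, 0 of 20 members past the test over the list alone), with HSPA8 at 2097 ± 247 and 3406 ± 1153 CPM. That call was lost without control 2 (adjusted p = 0.0612) and without knockdown 3 (adjusted p = 0.0588), and over the list alone 6 members rose without knockdown 2 and 2 without knockdown 3 or by DESeq2.

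Genes of cholesterol synthesis were lower. Of 24 measured members, 15 fell and 0 rose when adjusted over the list alone (median log2 fold change -0.58). MVD, mevalonate diphosphate decarboxylase, averaged 29.6 ± 5.7 CPM in controls and 12.7 ± 2.17 CPM in the libraries labelled knockdown, TM7SF2, a sterol reductase, 28.7 ± 3.21 and 11.3 ± 4.26 CPM, NSDHL 67.1 ± 13.4 and 36.1 ± 5.78 CPM, and LSS, lanosterol synthase, 105.3 ± 19.2 and 54.3 ± 15.9 CPM. Camera gave an adjusted p of 8.31e-11 (adjusted p = 0.65 with an estimated correlation), and edgeR called 0 members over all genes. The number that fell was 4 without control 2 or knockdown 1, 12 without control 1 or knockdown 2 and 17 without control 3 or knockdown 3.

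Fatty acid genes were lower in both directions of the pathway. In synthesis and desaturation, 6 of 25 members fell and 1 rose over the list alone (median -0.27, camera adjusted p = 0.000209, adjusted p = 0.65 with an estimated correlation). FADS2, a desaturase, averaged 142 ± 34.9 and 56.6 ± 28.2 CPM and ACLY, ATP citrate lyase, 650.7 ± 71.7 and 369.2 ± 133 CPM, while the member that rose was GPAM, an acyltransferase (64.2 ± 3.72 and 91.8 ± 18.2 CPM). In beta-oxidation, 3 of 37 members fell, namely ETFB (30.1 ± 5.39 and 13.98 ± 3.65 CPM), CPT1A (19.8 ± 2.25 and 11.9 ± 1.17 CPM) and ACAA2 (100.4 ± 7.71 and 58.1 ± 17.4 CPM), with a list median of -0.35 (camera adjusted p = 1e-06, adjusted p = 0.65 with an estimated correlation). Over all genes edgeR called 0 members of either list. The counts over the list alone were 0 for synthesis without control 1, control 2, knockdown 1 or knockdown 2, while 6 fell and 0 rose without control 3, 5 fell and 0 rose with the replicate block and 8 fell and 1 rose without knockdown 3. For beta-oxidation they were 18 without knockdown 3, 1 without control 1 and 0 without any of the other 4 libraries.

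Lysosome and autophagy genes were lower, with 12 of 45 members falling and 0 rising when adjusted over the list alone (median -0.29). Among them were GLB1, a lysosomal hydrolase (52.2 ± 4.53 and 34.3 ± 2.52 CPM), and GABARAPL2, an autophagosome protein (71.4 ± 5.65 and 48.1 ± 2.38 CPM). Camera gave an adjusted p of 2.92e-05 (adjusted p = 0.65 with an estimated correlation), and edgeR called 0 members over all genes. The number that fell was 0 without control 2 or knockdown 1, 1 without control 3, 4 without knockdown 2, 9 without control 1 and 22, with 1 rising, without knockdown 3.

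Respiratory chain genes encoded in the nucleus had a median of -0.30 over 69 members (camera adjusted p = 2.87e-08, adjusted p = 0.83 with an estimated correlation), and 0 passed over the list alone, or 31 without knockdown 3. ATP5F1A averaged 766.7 ± 44.1 and 471.2 ± 162 CPM, and the list medians of knockdown 1, 2 and 3 were -0.23, -0.72 and 0.00. Of 22 tricarboxylic acid cycle genes, IDH2 (36.5 ± 7.58 and 14.99 ± 4.73 CPM) fell over the list alone, with a list median of -0.16 (camera adjusted p = 0.0136, adjusted p = 0.83 with an estimated correlation). The call of this list was lost without knockdown 2 (adjusted p = 0.402) and without control 3 (adjusted p = 0.0598), and IDH2 was not called over all genes, nor over the list alone without knockdown 1. Over the list alone 4 members fell without knockdown 3 and 3 by DESeq2. In knockdown 2, 37.5% of uniquely aligned reads lay outside annotated genes, against 21.5% to 24.9% in the other 5 libraries.

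Genes of APP, its relatives, processing and clearance, named by the title, leaned lower. APP averaged 579.5 ± 25.2 CPM in controls and 437.3 ± 60.7 CPM in the libraries labelled knockdown (log2 fold change -0.41, standard error 0.16, edgeR adjusted p = 0.192), and APLP2 425.5 ± 38.9 and 330.9 ± 49.7 CPM (-0.36, adjusted p = 0.245). Of 36 members, 4 fell and 0 rose when adjusted over the list alone and edgeR called 0 over all genes. With 20.5% of all tested genes at an unadjusted edgeR p under 0.05, a count this small does not set the list apart. The 4 were MME, the amyloid-degrading protease neprilysin (5.9 ± 1.99 and 1.52 ± 0.416 CPM), the gamma-secretase subunits APH1B (16.2 ± 2.75 and 8.56 ± 1.84 CPM) and PSENEN (60.1 ± 7.82 and 37.1 ± 9.84 CPM), and NAE1, an APP-binding subunit of the NEDD8-activating enzyme (169.5 ± 6.58 and 107.2 ± 26.4 CPM). BACE1, the beta-secretase, averaged 31.4 ± 1.24 and 32.1 ± 11.2 CPM. In knockdown 1, 2 and 3 the list medians were -0.275, -0.126 and -0.137. The median over chromosomes was itself -0.109 in knockdown 2, so the list was hardly lower than other genes there. Over its members the list had a median log2 fold change of -0.14 (camera adjusted p = 0.0347, adjusted p = 0.65 with an estimated correlation). That call was lost without knockdown 1 (0.0651), knockdown 3 (0.0558) or control 3 (0.0736), with the stricter filter (0.0539) and with protein-coding genes only (0.0895), and the number that fell ranged from 1, without control 2, control 3 or knockdown 1, through 2 without control 1 to 6 without knockdown 2 and 8 without knockdown 3, with 1 member rising in each of these last cases.

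**Figure D2:**
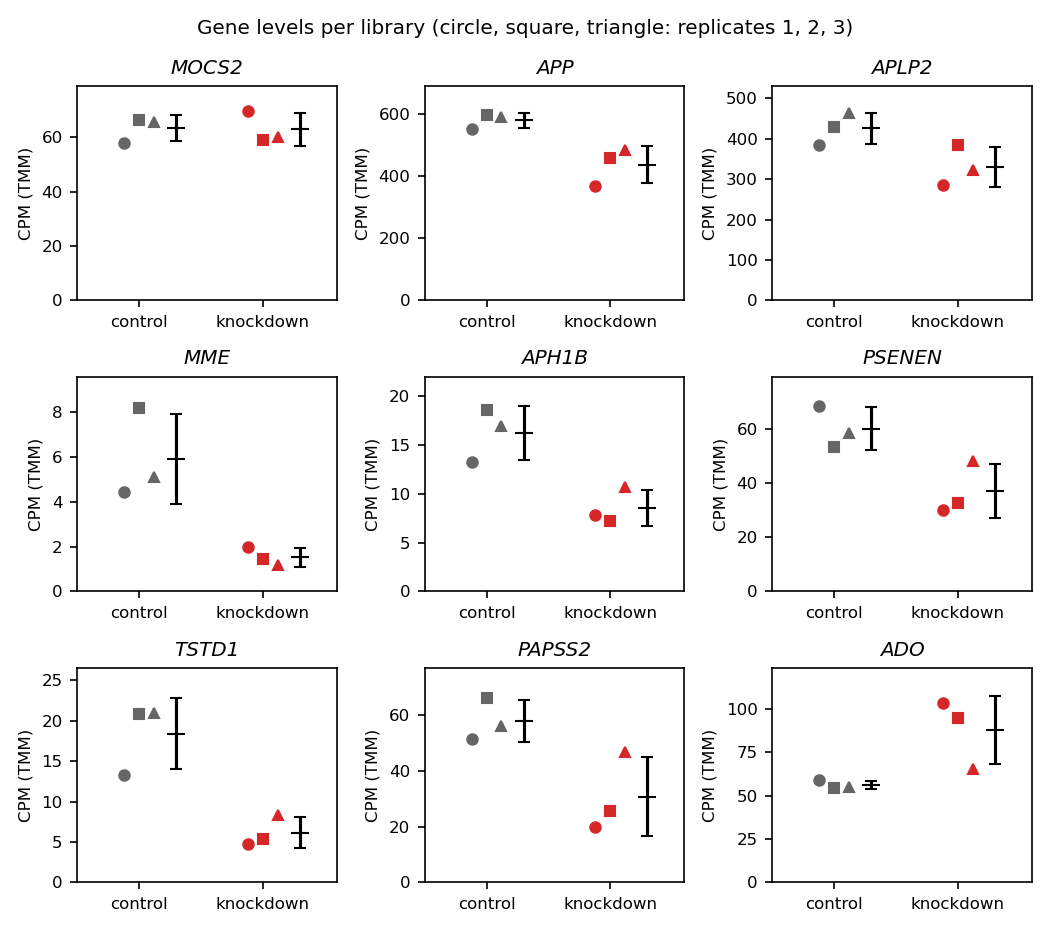
Levels in CPM (TMM-scaled) of 9 genes in each library, with the mean and SD over 3 libraries as black bars beside each group. MOCS2 averages 63.3 and 62.9 CPM, while MME averages 5.9 and 1.52 CPM and ADO 56.1 and 87.9 CPM in the controls and the libraries labelled knockdown.

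Sulfur amino acid genes went both ways. Of 33 members, 6 fell and 1 rose when adjusted over the list alone, and edgeR called 0 over all genes. Among the members that fell were TSTD1 (18.4 ± 4.38 and 6.17 ± 1.96 CPM), TST, the thiosulfate sulfurtransferase (18.7 ± 1.37 and 12.5 ± 0.498 CPM), ETHE1, the persulfide dioxygenase (7.53 ± 0.391 and 4.66 ± 0.579 CPM), and the sulfate-activating PAPSS1 (53.8 ± 7.66 and 34.7 ± 8.2 CPM) and PAPSS2 (58.1 ± 7.53 and 30.9 ± 14.1 CPM). ADO, cysteamine dioxygenase, rose (56.1 ± 2.41 and 87.9 ± 19.8 CPM). CDO1, cysteine dioxygenase, averaged 19.8 ± 1.96 and 29.1 ± 8.29 CPM and did not pass. The list had a median of -0.18 (camera adjusted p = 0.0701, adjusted p = 0.65 with an estimated correlation, and 0.0284 by camera without knockdown 1). Over the list alone, 1 member fell and 0 rose without any single library other than knockdown 3, and 13 fell and 5 rose without knockdown 3. With the replicate block or GC and length offsets 3 fell and 1 rose, and with no filter 8 fell and 3 rose.

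Markers of other cell types and of RNA fractions were checked in the same way. Among 25 fibroblast and mesenchymal markers, TAGLN, COL6A3, VIM and LOX rose and LUM, LGALS1 and PDGFRA fell over the list alone (camera adjusted p = 0.80), VIM from 804.7 ± 123 to 1277 ± 255 CPM. Without knockdown 1, 1 rose and 2 fell, without control 1, 2 rose and 4 fell, and without control 2, 2 rose and 2 fell. Without control 3, 3 rose and 3 fell, without knockdown 2, 3 rose and 4 fell, and without knockdown 3, 5 rose and 3 fell. Among kidney and epithelial markers KRT19 (110.8 ± 21.5 and 64.7 ± 12.3 CPM) and ESRP2 fell over the list alone (adjusted p = 0.31 by camera), and among neuronal markers CNTN1 fell (0.737), while 2 neuronal markers rose without control 3, without knockdown 3 or by DESeq2. Hematopoietic and endothelial markers gave 0 (0.94), but 1 of them fell without knockdown 2 and with DESeq2, voom, no filter, the stricter filter or the replicate block. Of the nuclear noncoding RNAs, MALAT1 rose (2179 ± 84.0 and 4115 ± 1667 CPM) and NEAT1 fell (336.3 ± 55.4 and 185 ± 70.4 CPM) over the list alone (0.457 by camera). The epithelial calls were 0 without control 1, control 3 or knockdown 1, and 1 without control 2 or knockdown 2, and those of noncoding RNAs were 0 without any 1 control or knockdown 1. Without knockdown 2, 0 noncoding RNAs rose and 2 fell, and with the replicate block 0 rose and 1 fell. The noncoding RNA calls were also 0 with upper-quartile factors, voom, the stricter filter or GC and length offsets. Without knockdown 3, 1 epithelial marker rose and 5 fell, and 4 noncoding RNAs rose and 2 fell. Mitochondrially encoded transcripts had list medians of -0.45, 0.86 and -0.55 in knockdown 1, 2 and 3 (0.917), and without knockdown 2 the list passed camera as lower (0.000457), with 6 of 15 members falling over the list alone. With all 6 libraries the estimated correlation within this list was 0.95 (camera adjusted p = 0.98 with it), so its members are far from independent.

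The remaining lists did not pass camera. Single members passed over the list alone in 3 of them, namely ATF5 among ATF4 and amino acid response genes (25.0 ± 5.77 and 81.2 ± 44.2 CPM, camera adjusted p = 0.442), BHLHE40 among hypoxia-inducible factor targets (84.7 ± 12.3 and 154.3 ± 45.5 CPM, 0.753) and IFI35 among interferon-stimulated genes (3.15 ± 0.327 and 0.827 ± 0.207 CPM, 0.80). In the ATF4 list 0 members were called without control 2, knockdown 1 or knockdown 2 and 2 rose without control 1, and in the hypoxia list 0 without any 1 control or knockdown 1. The replicate block also gave 0 in the ATF4 list, while 5 rose and 1 fell by DESeq2 and 7 rose and 3 fell with no filter. Without knockdown 3 the ATF4 list had 6 members rising and 9 falling, the hypoxia list 5 and 4, and the interferon list 5 and 5. The interferon list had 2 rising and 2 falling without knockdown 2, 4 rising and 3 falling with upper-quartile factors, GC and length offsets or protein-coding genes only, 4 and 4 by DESeq2, and 3 and 3 with the stricter filter. In the following lists 0 members passed over the list alone with all 6 libraries. The camera adjusted p was 0.0701 for ubiquitin-proteasome subunits, 0.0985 for glycolysis, 0.304 for the ATAC and SAGA acetyltransferase complexes, 0.387 for glutathione and NRF2 targets, and 0.457 for the unfolded protein response. It was 0.88 for iron-sulfur cluster assembly, 0.88 for mitochondrial ribosomal proteins, 0.917 for p53 targets and 0.917 for cytosolic ribosomal proteins. Without knockdown 3, however, 4 iron-sulfur genes rose and 5 fell over the list alone, 6 p53 targets rose and 4 fell, 1 glycolysis gene rose and 7 fell, 4 glutathione and NRF2 targets fell, 3 ATAC and SAGA genes rose, and 1 mitochondrial ribosomal protein gene rose and 2 fell. Without knockdown 2, 4 p53 targets fell, and by DESeq2 with all 6 libraries 3 p53 targets rose and 3 fell and 2 iron-sulfur genes and 2 genes of the unfolded protein response fell. Some lists passed camera when 1 library was left out. Glycolysis passed as lower without control 2 (0.0429), knockdown 1 (0.0188) or knockdown 3 (0.0128), and ubiquitin-proteasome subunits as lower without control 2 (0.0258), knockdown 1 (0.00122) or knockdown 3 (0.00579). The ATF4 list passed as higher without knockdown 1 (0.0254), and cytosolic and mitochondrial ribosomal proteins as higher without knockdown 2 (0.0137 each). Of the 31 lists, camera called 2 higher and 8 lower, and 0 were called with an estimated correlation or by fry.

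**Figure D3:**
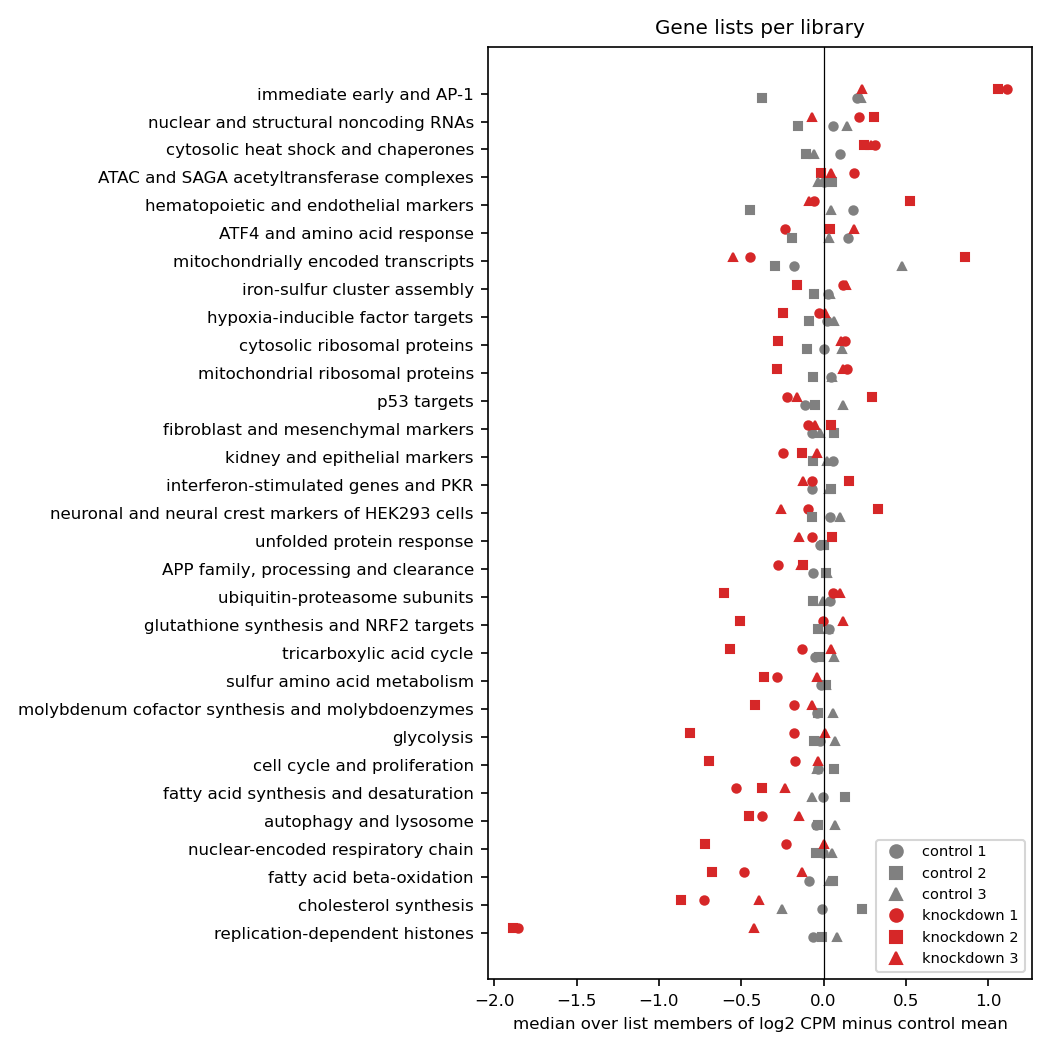
Median over the members of each of 31 gene lists of the log2 CPM in each library minus the control mean, controls in grey and libraries labelled knockdown in red. Histones lie at -1.85, -1.89 and -0.42 in knockdown 1, 2 and 3, and immediate early genes at 1.11, 1.06 and 0.24, with knockdown 3 nearest to the controls in both. For immediate early genes, knockdown 3 is level with control 1 and 3 (0.20 and 0.23).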

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

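Of the tests given here, the splits of the libraries and the bound on the share of MOCS2-DT reads were set out before their results were seen, and all others were chosen only after the result was seen.

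In the library labelled knockdown 2, 37.5% of uniquely aligned reads lay outside annotated genes, above all 3 controls (23.6% to 24.9%) by more than their range. No comparison uses these reads, but the reads assigned to genes also stood apart in knockdown 2. Protein-coding genes held 90.6% of them, against 93.5% to 95.0% in the other libraries. Mitochondrial ribosomal RNA held 1.33%, against 0.277% to 0.559%. The difference in composition therefore reaches the tested counts.

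The libraries labelled knockdown differ from each other more than the controls do, with a ratio of median SDs of 2.11. Correction for GC content and transcript length left it at 2.08, which argues against such a trend as the whole cause, and replicates 1 and 3 alone differed 1.71 times as much as the farthest control pair, which argues against knockdown 2 alone. Whether the library labelled knockdown 3 could be a control library was not decided by the bounds set: its slopes on the fold change of the other two, against a held-out control, were 0.205, 0.401 and 0.176, where all under 0.1 or all over 0.3 would have decided. A second test, tried because the first had not decided, gave r = 0.90 over chromosome medians (0.84 without the 2 farthest chromosomes) and 0.38 for a pair of controls (0.10 without the 2 farthest), over its bound of 0.3, and a further count, built from values already seen with its bound set once the outcome was known and so given only as a description, had knockdown 3 beyond all controls by more than their range, on the side of knockdown 1, in 4 of 5 chromosomes (0.254 on chromosome 15, controls -0.014 to 0.017). Chromosomes 5, 16 and 18, picked like the others by knockdown 1 alone, had knockdown 3 at 0.194, -0.24 and -0.273. Knockdown 1 lay at 0.21, -0.247 and -0.222 there, and all controls from -0.053 to 0.075. These values and those of chromosome 15 argue against a control library. On chromosome 14 the controls part from each other (-0.108 to 0.169), and knockdown 3 stood at 0.267. The immediate early list median of knockdown 3 (0.236) was level with that of control 3 (0.227). The bounds set were not met, so these tests did not decide, but the chromosome values given here argue against a control library.

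For the count of calls, the real grouping gave 0 genes by edgeR, the highest other split gave 0, and 10 of the 10 splits gave as many. Since the real grouping gave 0, any split would give as many, so this count cannot decide. With 3 against 3 there are also too few splits for a share under 0.05. At an unadjusted p under 0.05 the real grouping gave 3746 genes and the highest other split 1539, and by DESeq2 1145 and 86. The other splits mix both labels within each group, so a real group difference would widen their spread and lower their counts. These counts therefore do not give the number expected by chance.

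MOCS2 RNA was not lower in the libraries labelled knockdown. An exchange of labels between groups could account for this only if some libraries had clearly lower MOCS2, and the highest was 1.21 times the lowest; if the RNAi leaves MOCS2 RNA as it is, this value says nothing about the labels. Reads assigned to MOCS2-DT amounted to 8.54% of those assigned to MOCS2, so this transcript was counted at a much lower level. The share does not measure reads of MOCS2-DT counted under MOCS2. That depends on the strand setting, which is not given, so the share cannot decide. A higher dosage of chromosome 5 could hide a reduction, but MOCS2 minus the chromosome's median fitted value (0.158) was -0.17, with a lower bound of -0.46 at 2 standard errors and -0.57 on 4 residual degrees of freedom, just above the -0.58 of a 1.5-fold reduction, so a smaller reduction stays open. An RNAi that acts on translation or on 1 isoform stays open and untested, as does a knockdown that had been lost by the time of RNA extraction.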

How the results depend on the processing

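MOCS2 stayed far from the threshold under every alternative, with a log2 fold change of 0.009 with upper-quartile factors, 0.01 with protein-coding genes only, and -0.094 to 0.027 when single libraries were left out. Against 0 higher and 0 lower genes by edgeR (1813 and 1933 at an unadjusted p of 0.05), DESeq2 called 559 and 586 and the fit with no filter 694 and 880; the cause was not tested. Leaving out single libraries gave 0 to 1232 higher and 0 to 1583 lower. Of the 1145 DESeq2 calls, 1089 were among the 2815 made without knockdown 3, which shares 5 libraries with it. DESeq2 size factors, upper-quartile factors, voom, the stricter filter, glmTreat, GC and length offsets and protein-coding genes only each gave 0. The replicate block gave 6 higher and 13 lower; the numbers did not pair the samples (correlations of 0.114, -0.167 and -0.125). Against 2 lists higher and 8 lower by camera, an estimated correlation gave 0 and 0 and fry gave 0 and 0. Both camera runs used the same fit and differ only in the correlation setting. Among the called lists the estimate ran from 0.042 for the APP list to 0.76 for histones, against the preset 0.01. The camera calls therefore rest on the preset value. Leaving out single libraries gave 1 to 4 higher and 7 to 11 lower. The cause of the differences by fry and by left-out libraries was not tested. Upper-quartile factors and voom each added cell cycle and ubiquitin-proteasome, the block these and glycolysis, and no filter these and the sulfur list; the stricter filter and protein-coding genes only lost the APP list. Over the list alone, beta-oxidation had 6 or 7 members lower with upper-quartile factors, DESeq2, voom or the block and 13 with no filter, against 3. By contrast, glmTreat left 2 cholesterol synthesis members lower (against 15), 0 of lysosome and autophagy (12) and 0 of either fatty acid list. It left 1 member lower in the APP list (against 4) and 1 in the sulfur list (6). Histones kept 20 lower (against 25) and immediate early genes 9 higher (17). Cell cycle went from 0 and 0 to 1 higher and 8 lower with voom, 1 and 14 with the block and 2 and 15 with no filter, and the respiratory chain to 14 lower with no filter. Of 77 named genes, only MOCS2 changed sign under any alternative, and 1222 of 1228 pairs of gene and setting kept their direction. Many of the named genes were chosen for a small p in these same counts. Those taken at an unadjusted p under 0.001 also had to show no overlap between groups. Leaving out a library can hardly reverse the sign of such genes, and the other settings refit the same counts. Their kept direction is therefore largely a condition of their choice and not a result. Offsets and protein-coding genes only were added after seeing the data. In 15514 genes (84.9% of those tested), the squared coefficient of variation from counting alone (the inverse of the mean count) was under the squared common biological coefficient of variation. The latter was estimated here without TMM factors.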

Other observations

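The tests of this part were all chosen after the result was seen.

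Clustered protocadherin genes, which encode adhesion molecules of neural cells, lay together on the higher side in the libraries labelled knockdown (chromosome 5, 140806929 to 141512979). Of 38 tested coding members, 37 had a positive log2 fold change, with a median of 0.91, and 20 had all 3 libraries labelled knockdown above all 3 controls. Chance gives 5% above, and 12.5% of all tested genes lay above. Neighbouring members are not independent genes, so their share cannot be tested against these rates. The median difference of chromosome 5 was itself 0.146. edgeR called 0, with 20 at an unadjusted p under 0.05, and DESeq2 called 15 higher and 0 lower. PCDHA10 averaged 9.91 ± 0.635 CPM in controls and 26.7 ± 6.39 CPM in the libraries labelled knockdown (edgeR adjusted p = 0.0558), and PCDHB2 7.69 ± 0.801 and 24.3 ± 9.41 CPM (0.0634). Neighbouring members share near-identical sequence and exons, so single values are uncertain.

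Chromosome medians differed between the groups, but not alike in all libraries. Median log2 differences were 0.22 on chromosome 14, 0.17 on chromosome 15 and 0.15 on chromosome 5, and -0.20 on chromosome 16 and -0.19 on chromosome 18. Knockdown 2 was lower on most chromosomes (median -0.109 over 23). Relative to that median, set after the values were seen, it was raised on chromosomes 14 (0.20, control 3 at 0.18), 5 (0.13, controls at most 0.02) and 15 (0.08, controls at most 0.00, knockdown 1 and 3 at 0.26 and 0.25). It lay at -0.05 on chromosome 16 (control 3 at -0.04) and 0.00 on chromosome 18, so it did not share the lower medians. In bins of 10 Mb of the group difference, 9 of 9 on chromosome 14, 9 of 9 on chromosome 15 and 15 of 18 on chromosome 5 were above 0, and 0 of 9 on chromosome 16 and 0 of 8 on chromosome 18. A trend with GC content and length is argued against, since correction left 99.1% of the spread of the chromosome medians. A candidate explanation is a chromosome dosage difference between control and knockdown cultures: over 23 chromosomes, knockdown 1 minus control 1 and knockdown 3 minus control 2, which share no library, correlated with r = 0.90 (permutation p = 1e-05, the smallest that 100000 permutations give) and rho = 0.81 (permutation p = 2e-05), and r = 0.84 without the 2 farthest chromosomes. Knockdown 2 minus control 3 gave r = 0.50 (permutation p = 0.016) and rho = 0.61 (0.0021) with the first of these, and r = 0.35 (permutation p = 0.098) and rho = 0.49 (0.02) with the second, or r = 0.58 and 0.54 without the 2 farthest chromosomes. Control 3 minus control 2 gave r = 0.38 (permutation p = 0.073) and rho = 0.32 (0.14) with knockdown 1 minus control 1, and r = 0.10 without the 2 farthest. These p-values are not adjusted over the 4 pairs compared. DNA was not analysed here, and a regulatory difference along these chromosomes remains open.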
